A study of Mus musculus with 20 samples.

How the data were processed

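RNA was sequenced from sorted mouse intestinal crypt cells and from intestinal organoids, in 20 libraries prepared from total RNA with the NEBNext Ultra RNA kit, per the labels. The tissue set holds 12 libraries of cells sorted by flow cytometry on the Lgr5-EGFP reporter, which marks crypt stem cells: WT Lgr5-high, WT Lgr5-low, and cells labelled *Mettl3*-/- at day 4 in both gates with 2 libraries each, cells labelled *Mettl3*-/- at day 3 with 1 library per gate, and cells labelled *Mettl3*-/- at day 6 with 2 libraries whose labels name no gate. The column header of the first day 6 library names a low gate, and the labels were followed. Per the labels' protocols, mice received tamoxifen at 20 mg/ml for 4 days. The WT tissue libraries are labelled untreated, while the same protocols say that *Mettl3*fl/fl mice without Cre also received tamoxifen. Knockout and WT tissue may thus differ in tamoxifen, which the labels do not settle. The organoid set holds 8 libraries, 2 in each of 4 groups: WT (ethanol for 2 days) and 3 labelled *Mettl3*-/- (4-OHT for 2 days). Of the 3, 1 has no factor in its labels, 1 has AKF (retroviral *Ascl2*, *Klf9* and *Fosb*) and 1 AKFP (the same with *Purb*). Knockout and WT organoids may thus differ by an effect of 4-OHT itself. Only the titles of these 2 groups hold "m3-flag", whose meaning is not stated, so AKF and AKFP may differ from both by it.

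The deposited tissue files hold FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) per gene, per the file headers. The header of the deposited organoid table names no unit. Its values were taken as FPKM because the table has the same gene rows, number format and range as the tissue files. Per the submitters' processing notes, HISAT2 2.1.0, StringTie 1.3.3b and the mm10 build were used, and the notes do not say which step each tool did. Gene identifiers were matched to symbols and positions in GENCODE M21, whose build GRCm38 is mm10: 54723 of the 54838 gene rows had a symbol, 115 had none, and 101 symbols were shared by more than 1 identifier. The kit and the counting are not stated to keep strand, so genes with an antisense partner, like genes with near-identical copies, have uncertain values. No 2 libraries were identical. Depth was estimated from the smallest steps between values of 21839 genes with 1 exon and 1 transcript, and came to between 14.9 and 25.4 (in units of 1e6 fragments) per library. This is a rough estimate.

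Values were analysed as log2(FPKM + 1) with no further scaling. Fold changes on that scale understate the change of genes at low FPKM. A gene was tested where it reached 1 FPKM in at least 2 libraries of the fit, which left 12899 genes in tissue and 12657 in organoids. limma 3.58.1 (lmFit, and eBayes with a trend, in R 4.3.3) was fitted with 1 mean per group to the 10 tissue libraries of the groups with 2 libraries, and to the 8 organoid libraries, so that all groups of a fit shared 1 estimate of the spread. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and calls at an adjusted p under 0.05. In all, 13 comparisons were tested. The day 3 libraries stayed outside the fit and are given without a test, as differences from the mean of the WT libraries of their gate, with the percentile of each list's median among 10000 random lists of the same size and matched mean expression. Every p-value below measures only the spread between these libraries, because the labels do not say whether libraries of a group came from separate animals or cultures.

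The genes named for each comparison followed a rule set, like the gene lists and most other settings, before the data were examined: the 8 largest rises and the 8 largest falls among called genes whose libraries did not overlap between the groups and whose mean reached 5 FPKM in either group, without predicted, unnamed or small RNA genes, or, where fewer than 3 passed, the 3 with the smallest unadjusted p, said not to pass. *Mettl3*, *Lgr5*, *Ascl2*, *Klf9*, *Fosb*, *Purb*, *Olfm4*, *Mki67*, *Myc* and *Cdkn1a* were always named, with the 3 genes of smallest p in each list. Some genes that this rule names are not reported here. The 25 lists were intestinal stem cell markers, Wnt targets, cell cycle, reserve stem cell markers, fetal-like and YAP targets, markers of Paneth, goblet, enteroendocrine and tuft cells and of enterocytes, Notch and secretory choice, m6A machinery, immediate early and dissociation genes, interferon response, p53 targets, integrated stress and unfolded protein response, cell death, MHC class II, fatty acid oxidation, cholesterol synthesis, ribosome biogenesis, intestinal region, immune cells, stromal and endothelial cells, and the overexpressed factors. The last list holds the 4 factors that the labels name, so it is not independent of the study's choice. Lists were tested with limma's camera at a preset correlation of 0.01, then with an estimated correlation, and with fry, which asks only whether a list's genes moved one way on balance, with Benjamini-Hochberg adjustment over the lists of a comparison. Each p-value given by camera is the one with an estimated correlation, with which no list passed in any comparison (lowest adjusted p 0.136).

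Overlaps of calls are given with the number that independent calls would share. For AKF and AKFP, unchanged groups were simulated 20 times against the shared knockout libraries. Limma was tested in 5 simulations built from these libraries, each with 200 changed genes. For Lgr5-high knockout at day 4 it called 19.2% of 2-fold changes, 90.8% of 4-fold changes and 0.05% of unchanged genes. In knockout organoids these were 89.6%, 100% and 0.05%. These rates may not hold where more genes change or libraries stand apart. The other settings were pseudocounts of 0.1 and 5, a filter at 5 FPKM and no filter, median-of-ratios scaling, quantile normalization, the replicate number as a block, only the compared groups in the fit, and leaving out each library in turn. Chosen after seeing the data were equal FPKM sums, leaving out the 2 tissue libraries that stood apart, and taking out a transcript length trend (loess, span 0.5). A fit for count tables does not apply to FPKM and was not run. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.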

Results

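*Mettl3* encodes the catalytic subunit of the m6A RNA methyltransferase and is the gene the labels give as deleted. Its level did not separate knockout from WT, except with AKFP (higher) and, against WT Lgr5-high, at days 3 and 6 (lower). In sorted tissue cells it stood at 4.86 and 4.58 FPKM in the WT Lgr5-high libraries and 4.23 and 3.42 in WT Lgr5-low. It stood at 3.61 and 3.49 in the single libraries labelled knockout at day 3 (Lgr5-high and Lgr5-low), 4.99 and 3.51 in knockout Lgr5-high and 3.67 and 2.75 in knockout Lgr5-low at day 4, and 3.54 and 3.10 in knockout at day 6. In organoids it stood at 3.23 and 3.56 FPKM in WT, 3.62 and 3.47 in knockout, 3.33 and 3.57 in knockout with AKF, and 3.78 and 4.22 in knockout with AKFP. The fitted changes of *Mettl3* were -0.14 and -0.20 at day 4 (limma adjusted p = 0.777 and 0.767) and 0.05 in organoids (adjusted p = 0.703). A value per gene cannot check the deletion of an exon, because transcripts without that exon still give fragments over the rest of the gene (chromosome 14, 52294841 to 52305128, mm10). "Knockout" below therefore means the library labelled *Mettl3*-/-.

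The first comparison asks how the Lgr5-high and Lgr5-low gates differ in WT crypts. Some stem cell markers, *Lgr5* and *Ascl2* among them, were higher in Lgr5-high cells, and some enterocyte genes, such as *Apoa1*, were higher in Lgr5-low cells. Of the listed goblet, enteroendocrine, Paneth and tuft markers only *Zg16* of goblet cells and *Sst* of enteroendocrine cells passed, both higher in Lgr5-low. *Lgr5*, the R-spondin receptor whose reporter set the gates (chromosome 10, 115450311 to 115587780), was higher in Lgr5-high by 2.62 ± 0.36 on the log2 scale (SE), at 10.3 ± 0.175 against 0.844 ± 0.183 FPKM (SD, n = 2), with limma adjusted p = 0.0172. *Ascl2*, a transcription factor of crypt stem cells, was higher by 2.08 ± 0.32, at 39.6 ± 0.641 against 8.66 ± 1.05 FPKM (adjusted p = 0.0233). *Apoa1*, an apolipoprotein of enterocytes, was lower in Lgr5-high at -4.35 ± 0.57 (adjusted p = 0.0162), and *Zg16*, a goblet cell lectin, at -3.36 ± 0.45 (adjusted p = 0.0163). Each gene called here had both libraries of one gate above both of the other. Of the stem cell markers, 9 of 24 rose (22 rose adjusted over the list alone, adjusted p = 0.195 with an estimated correlation), among them *Igfbp4*, which binds insulin-like growth factors (2.27), *Rgmb* (1.87) and *Fstl1* (1.74). Among Wnt targets 7 of 17 rose (12 rose adjusted over the list alone, adjusted p = 0.195 with an estimated correlation). The rises included the receptors *Tnfrsf19* (2.33) and *Cd44* (1.59). *Ccdc3* (2.25), *Bex1* (1.97) and the cytochrome *Cyp2e1* (2.0) were higher as well. In the enterocyte list 5 of 16 fell (14 fell adjusted over the list alone, adjusted p = 0.291 with an estimated correlation). The falls included the retinol carrier *Rbp2* (-3.61) and the brush border phosphatase *Alpi* (-3.27). The largest falls held the apolipoprotein *Apoa4* (-4.33), the peptidase *Ggt1* (-3.73), the glutathione transferase *Gsta1* (-3.59) and the fatty acid carrier *Fabp1* (-3.57). Among goblet genes 1 of 9 fell (6 fell adjusted over the list alone, adjusted p = 0.195 with an estimated correlation). Among enteroendocrine genes 1 of 14 fell (9 fell adjusted over the list alone, adjusted p = 0.390 with an estimated correlation), the fall being that of the hormone gene *Sst* (-2.25). Among Paneth genes 0 of 11 passed (0 adjusted over the list alone, median -0.17, adjusted p = 0.823 by camera). Among tuft genes 0 of 8 passed (0 adjusted over the list alone, median -0.70, adjusted p = 0.626 with an estimated correlation). Among cell cycle genes 0 of 29 passed (0 adjusted over the list alone, median 0.34, adjusted p = 0.533 with an estimated correlation). *Olfm4*, a secreted marker of crypt stem cells, stood at 2.53 (adjusted p = 0.0998). *Myc* stood at 1.1 (adjusted p = 0.153) and *Mki67*, a marker of cycling cells, at 0.44 (adjusted p = 0.612), and none of these passed. The histone gene *Hist2h2aa1*, which has a near-identical copy, read 9.67 and 7.84 FPKM in Lgr5-high and was listed at 0 in both Lgr5-low libraries. By limma 155 of 12899 genes passed, 48 higher and 107 lower in Lgr5-high. With only the compared groups in the fit 1432 passed, with equal FPKM sums 57 and with no filter 32. With 2 libraries per group the count rested on every one of them. It was 1 and 0 without the first and second WT Lgr5-high library and 7 and 3 without the first and second Lgr5-low library. These fits leave 1 library in a group, too few to judge the lists.

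The next comparison asks what changed in Lgr5-high cells 4 days into the *Mettl3* deletion. Some interferon-induced genes, such as *Isg15*, the p53 targets *Phlda3* and *Cdkn1a* and some hormone genes were higher in the knockout, while some immediate early genes, such as *Fosb*, were lower. Most members of these lists did not pass, and no cell cycle gene did. *Isg15*, an interferon-induced ubiquitin-like protein (chromosome 4, 156199424 to 156200818), rose by 3.93 ± 0.50, at 33.2 ± 3.18 against 1.24 ± 0.0217 FPKM (SD, n = 2; limma adjusted p = 0.0164). *Phlda3*, a p53 target that restrains Akt, rose by 2.89 ± 0.23, at 17.4 ± 3.29 against 1.46 ± 0.225 FPKM (adjusted p = 0.00221). *Fosb*, an immediate early transcription factor and one of the overexpressed factors (chromosome 7, 19302696 to 19310051), changed by -1.97 ± 0.32, at 24.8 ± 1.90 against 100 ± 11.1 FPKM (adjusted p = 0.0337). Each gene called here had both knockout libraries on the same side of both WT libraries. In the interferon response list 7 of 18 rose (12 rose adjusted over the list alone, adjusted p = 0.258 with an estimated correlation). Among the risers were the antiviral membrane protein *Bst2* (1.99) and the RNA-sensing enzyme *Oas1a* (1.91). The interferon-induced GTPases *Igtp* (3.66), *Tgtp1* (3.14) and *Tgtp2* (3.18) were among the largest rises, the last pair being near-identical copies whose values are uncertain. Among p53 targets 2 of 17 rose (8 rose and 2 fell adjusted over the list alone, adjusted p = 0.209 with an estimated correlation), the other being the cell cycle inhibitor *Cdkn1a* (1.48 ± 0.28, adjusted p = 0.0497). Among enteroendocrine genes 5 of 14 rose (14 rose adjusted over the list alone, adjusted p = 0.258 with an estimated correlation). Those that rose included the hormone genes *Ghrl* (3.13), *Sst* (3.05) and *Tac1* (3.19) and the granule protein *Chga* (3.02). Among goblet genes 1 of 9 rose (7 rose adjusted over the list alone, adjusted p = 0.209 with an estimated correlation), the rise being that of the mucus peptide *Tff3* (1.77). Among immediate early and dissociation genes 5 of 17 fell (9 fell adjusted over the list alone, adjusted p = 0.209 with an estimated correlation). The falls included *Jun* (-1.57), the phosphatase *Dusp1* (-1.83) and the mRNA decay factor *Zfp36* (-1.46).

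Other named genes of Lgr5-high cells at day 4 were the metallothionein *Mt2*, which binds metals (3.48 ± 0.31, limma adjusted p = 0.00352), and the defensin *Defa25* (3.35), which has close copies. With them stood *Psat1*, an enzyme of serine synthesis (1.16), all higher in both knockout libraries. Lower in both were the endothelin *Edn2* (-2.66 ± 0.32, adjusted p = 0.0126), the lipid droplet enzyme *Hsd17b13* (-2.57), *Pbld1* (-2.14), and *Cyp2e1* (-2.01). So were the carboxylesterase *Ces1d* (-1.98), the endocytic receptor *Lrp1* (-1.84), the kinase *Pdk4* (-1.70) and *Fstl1* (-1.35), the 1 stem cell marker of 24 that passed. For the stem cell markers 1 of 24 fell (3 fell adjusted over the list alone, adjusted p = 0.545 with an estimated correlation). *Lgr5* stood at 4.16 ± 2.61 against 10.3 ± 0.175 FPKM (SD, n = 2), a change of -1.23 (adjusted p = 0.145) that did not pass. *Olfm4* (-0.89, adjusted p = 0.505), *Ascl2* (-0.15, adjusted p = 0.832), and *Klf9* (-1.52, adjusted p = 0.149) did not pass. *Purb* (-0.45, adjusted p = 0.575), *Myc* (0.17, adjusted p = 0.813) and *Mki67* (-0.11, adjusted p = 0.895) did not pass either. Among Wnt targets 0 of 17 passed (0 adjusted over the list alone, median -0.06, adjusted p = 0.864 by camera). Among cell cycle genes 0 of 29 passed (0 adjusted over the list alone, median -0.06, adjusted p = 0.929 by camera), with a mean of 0.03 that lay on the other side of 0. Among genes of the m6A machinery 0 of 16 passed (0 adjusted over the list alone, median -0.13, adjusted p = 0.929 by camera). The first knockout library of this gate stood apart. Defensin and lysozyme genes were at 27.6% of its summed FPKM, against 20.2% in the second and 22.9% and 16.6% in WT. Whether hormone and mucus genes moved with that library was not tested. By limma 136 genes passed, 94 higher and 42 lower, of which 69.1% were higher. With only the compared groups in the fit 0 passed, with equal FPKM sums 34 and with no filter 29. The share was 55.9% with median-of-ratios scaling, 55.1% with quantile normalization and 49.5% after a transcript length trend was taken out. The count was 1 and 4 without the first and second WT library, 45 without the first knockout library and 699 without the second. The immediate early list mean (log2) was 5.38 and 5.4 in the knockout libraries and 6.46 and 6.54 in WT. This fall did not rest on 1 library.

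The same question in the Lgr5-low gate at day 4 gave fewer calls, with *Isg15* and *Phlda3* again higher in the knockout. Most interferon genes and p53 targets did not pass. *Cbr3*, a carbonyl reductase, rose by 3.71 ± 0.24, at 20.7 ± 2.12 against 0.666 ± 0.150 FPKM (SD, n = 2; limma adjusted p = 0.00149). *Isg15* rose by 3.32 ± 0.50, at 51.5 ± 29.1 against 4.48 ± 3.59 FPKM (adjusted p = 0.0392). *Phlda3* rose by 3.16 ± 0.23, at 13.1 ± 2.73 against 0.566 ± 0.168 FPKM (adjusted p = 0.00149). *Acta1*, a skeletal muscle actin, rose by 2.62, and *Edn2* stood lower at -2.56 (adjusted p = 0.0269). Each called gene had both knockout libraries on one side of both WT libraries. In the interferon response list 4 of 18 rose (17 rose adjusted over the list alone, adjusted p = 0.235 with an estimated correlation). Higher members were *Oasl2* (2.04), *Rtp4* (1.87) and *Bst2* (1.72). Outside the list *Igtp* (3.54) and *Ifit1bl1* (2.96) rose, as did *Tgtp1* (3.07) and *Tgtp2* (3.22), whose copies make them uncertain. Among p53 targets 1 of 17 rose (10 rose and 1 fell adjusted over the list alone, adjusted p = 0.233 with an estimated correlation). Among immediate early genes 1 of 17 fell (9 fell adjusted over the list alone, adjusted p = 0.235 with an estimated correlation), the member being *Zfp36* (-1.45), while *Fosb* stood at -1.91 (adjusted p = 0.0513) and did not pass. *Psat1* (1.58) rose in this gate too. The falls held *Hsd17b13* (-2.34), *Pbld1* (-2.20), the gluconeogenic enzyme *Fbp1* (-2.0), and *Rgn* (-1.96). They also held the bicarbonate transporter *Slc4a5* (-1.58), the cytochrome *Cyp39a1* (-1.54) and the clock repressor *Nr1d1* (-1.61), which overlaps an antisense gene and is uncertain. Among enteroendocrine genes 0 of 14 passed (6 rose adjusted over the list alone, median 1.37, adjusted p = 0.495 with an estimated correlation). Among stem cell markers 0 of 24 passed (2 rose and 1 fell adjusted over the list alone, median 0.08, adjusted p = 0.884 by camera). *Lgr5* (0.01, adjusted p = 0.997), *Ascl2* (-0.21, adjusted p = 0.850), *Olfm4* (-0.23, adjusted p = 0.933) and *Cdkn1a* (1.25, adjusted p = 0.109) did not pass. By limma 61 genes passed, 36 higher and 25 lower. With only the compared groups in the fit 1 passed, with equal FPKM sums 6 and with no filter 21. The count fell without each library in turn, but 1 library in a group is too few to judge the lists.

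**Figure D1:**
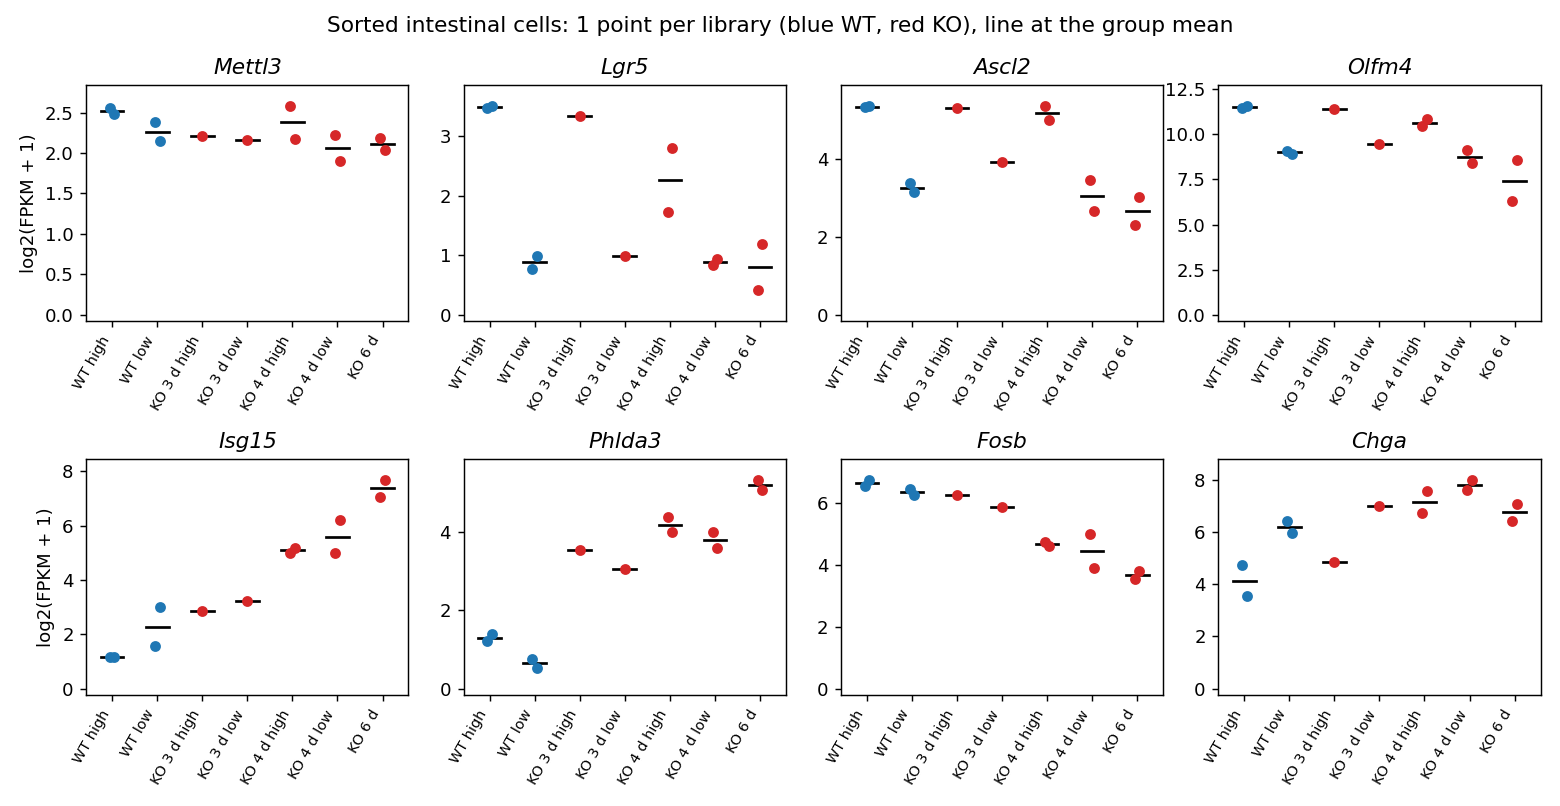
Each panel shows log2(FPKM + 1) of 1 gene in 7 groups of sorted cells, 1 point per library (blue WT, red knockout) with a line at the group mean. *Isg15* and *Phlda3* are higher and *Fosb* lower in each knockout library at days 4 and 6 than in the WT libraries. *Mettl3* overlaps between them and *Lgr5* is lower in both day 6 libraries than in either WT Lgr5-high library.

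Whether the knockout kept the difference between the gates at day 4 was asked next. *Ascl2* stood at 35.8 ± 6.43 against 7.64 ± 3.29 FPKM (SD, n = 2) in knockout Lgr5-high and Lgr5-low, *Lgr5* at 4.16 ± 2.61 against 0.849 ± 0.0805 FPKM, and the brush border enzyme *Alpi* lay the other way at -2.72. None of these passed (limma adjusted p = 0.0807, 0.141 and 0.0930), and both libraries of a gate lay on one side of both of the other for each of them. The 3 smallest p-values in each direction belonged to *Bex1* (2.03, adjusted p = 0.0658), *Igfbp4* (1.56, adjusted p = 0.0807) and *Ascl2*, and to the membrane protein *Mall* (-2.01, adjusted p = 0.0807), the anion exchanger *Slc26a6* (-1.98, adjusted p = 0.0807) and *Tm6sf2* (-1.81, adjusted p = 0.0807), which acts in lipid secretion. For stem cell markers 0 of 24 passed (16 rose adjusted over the list alone, median 0.90, adjusted p = 0.420 with an estimated correlation). For Wnt targets 0 of 17 passed (10 rose adjusted over the list alone, median 0.82, adjusted p = 0.420 with an estimated correlation). For enterocyte genes 0 of 16 passed (16 fell adjusted over the list alone, median -2.36, adjusted p = 0.420 with an estimated correlation). By limma 0 genes passed and 2417 had an unadjusted p under 0.05. After a transcript length trend was taken out 125 passed (23 higher, 102 lower). The count of 0 rose in some fits without 1 library, which leave 1 library in a group. Across genes, the gate differences in WT and in knockout had Pearson r = 0.656 (jackknife SE 0.174 over 8 libraries, 0.506 to 0.702 with 1 left out), where genes are not independent replicates. The test of the difference itself, the knockout change in Lgr5-high minus that in Lgr5-low, called 2 genes of 12899 (223 at an unadjusted p under 0.05), both lower. They were *Hist2h2aa1* (-3.28, adjusted p = 0.00519) and the predicted gene *Gm27640* (-3.87, adjusted p = 0.00534), the second outside the naming rule and chosen after its values were seen. Both calls were lost in some fits without 1 library, which leave 1 library in a group. *Lgr5* had a difference of -1.23 (adjusted p = 0.963). No difference between the gates in the knockout change was shown for the lists, whose adjusted p was 0.855 or higher with an estimated correlation. Of the genes higher in knockout, 32 were called in both gates (0.3 for independent calls), and of those lower, 11 (0.1). The gates shared 1 estimate of the spread, and their same-numbered libraries correlated (0.44 in WT, 0.34 in knockout), so these calls were not independent.

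At day 6 the question is how far the knockout cells, whose labels name no gate, had moved from each WT gate. The header of the first library names a low gate, so a difference from WT Lgr5-high is not separable from one between gates. Most interferon response genes and p53 targets were higher than in both gates, as was *Ly6a*, and immediate early genes such as *Fosb* and *Jun* were lower than in both. *Isg15* rose by 6.21 ± 0.50 over WT Lgr5-high and by 5.09 ± 0.50 over Lgr5-low, at 168 ± 52.8 against 1.24 ± 0.0217 FPKM in Lgr5-high (SD, n = 2; limma adjusted p = 4.03e-04 and 0.00157). *Ly6a*, the surface protein Sca-1 that marks regenerating epithelium, rose by 5.82 and 5.0 (adjusted p = 0.00160 and 0.00398). *Phlda3* rose by 3.92 and 4.57, and *Fosb* stood at -2.99 and -2.71 (adjusted p = 0.00119 and 0.00267). Each gene called at day 6 and named here had both knockout libraries on one side of both libraries of the WT gate concerned. In the interferon response list 15 of 18 rose (17 rose adjusted over the list alone, adjusted p = 0.223 with an estimated correlation) against Lgr5-high. Against Lgr5-low 13 of 18 rose (16 rose adjusted over the list alone, adjusted p = 0.307 with an estimated correlation). The rises included *Rtp4* (3.63 and 3.53) and *Bst2* (3.11 and 3.13). Among p53 targets 13 of 17 rose (13 rose and 1 fell adjusted over the list alone, adjusted p = 0.198 with an estimated correlation) against Lgr5-high. Against Lgr5-low 11 of 17 rose (11 rose adjusted over the list alone, adjusted p = 0.136 with an estimated correlation). Among the risers were *Cdkn1a* (3.03 and 1.73) and the kinase *Plk2* (1.61 and 1.97). Among fetal-like genes and YAP targets 6 of 9 rose, 1 fell and 2 did not pass (7 rose and 1 fell adjusted over the list alone, adjusted p = 0.298 with an estimated correlation) against Lgr5-high. Against Lgr5-low 6 of 9 rose (7 rose and 1 fell adjusted over the list alone, adjusted p = 0.352 with an estimated correlation). Those that rose included the EGF family ligand *Areg* (3.28 and 2.75) and the calcium-binding *S100a6* (4.86 and 3.47). The cornified envelope genes *Sprr2a1*, *Sprr2a2* and *Sprr2a3* had the largest rises over Lgr5-high outside the lists (7.70, 7.48 and 5.82), and their near-identical copies make each value uncertain. Of the immediate early genes 9 of 17 fell (9 fell adjusted over the list alone, adjusted p = 0.378 with an estimated correlation) against Lgr5-high. Against Lgr5-low 7 of 17 fell (8 fell adjusted over the list alone, adjusted p = 0.352 with an estimated correlation). The falls included *Jun* (-2.25 and -1.74).

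Most stem cell markers at day 6 were lower against the Lgr5-high gate, and most did not pass against Lgr5-low, the gate that the header of the first library names. *Olfm4* (chromosome 14, 79984081 to 80023139) stood at 231 ± 217 against 2960 ± 144 FPKM (SD, n = 2), a change of -4.09 ± 0.62 (limma adjusted p = 0.00372). *Lgr5* changed by -2.69 (adjusted p = 0.00239) and *Ascl2* by -2.66 (adjusted p = 0.00165). Against Lgr5-low the same genes did not pass, at -1.56, -0.08 and -0.59 (adjusted p = 0.148, 0.923 and 0.273). Of the stem cell markers 1 of 24 rose, 19 fell and 4 did not pass (1 rose and 20 fell adjusted over the list alone, adjusted p = 0.298 with an estimated correlation) against Lgr5-high. Against Lgr5-low 3 of 24 rose, 1 fell and 20 did not pass (3 rose and 1 fell adjusted over the list alone, adjusted p = 0.956 by camera), where the median was -0.11 and camera gave the upward direction. The Wnt feedback gene *Axin2* (-2.60), *Cdca7* (-2.56), the receptor *Notch1* (-2.62) and the Wnt antagonist *Sfrp5* (-3.83) fell against Lgr5-high. So did the urea transporter *Slc14a1* (-3.41) and the adrenergic receptor *Adra2a* (-3.32). Among cell cycle genes 1 of 29 rose, 8 fell and 20 did not pass (2 rose and 13 fell adjusted over the list alone, adjusted p = 0.561 with an estimated correlation) against that gate, such as the replication helicase subunit *Mcm6* (-1.37), and *Mki67* did not pass (-0.81, adjusted p = 0.120). Against Lgr5-low 1 of 29 rose, 0 fell and 28 did not pass (0 rose and 0 fell adjusted over the list alone, adjusted p = 0.910 by camera). The factors other than *Ascl2* and *Fosb* stood at *Klf9* (-1.47, adjusted p = 0.0503) and, past the threshold, *Purb* (-1.38, adjusted p = 0.0333). Of enterocyte genes 9 of 16 rose (11 rose adjusted over the list alone, adjusted p = 0.381 with an estimated correlation) against Lgr5-high. Higher members were *Apoa1* (5.48) and *Apoa4* (5.43). Of enteroendocrine genes 12 of 14 rose (12 rose adjusted over the list alone, adjusted p = 0.298 with an estimated correlation) against that gate, and against Lgr5-low 2 of 14 rose (2 rose adjusted over the list alone, adjusted p = 0.689 with an estimated correlation). The rises over Lgr5-high included the peptide *Nts* (4.78). Of goblet genes 8 of 9 rose (8 rose adjusted over the list alone, adjusted p = 0.223 with an estimated correlation) against Lgr5-high, and against Lgr5-low 2 of 9 rose (4 rose adjusted over the list alone, adjusted p = 0.437 with an estimated correlation). A member that rose over Lgr5-high was the mucin *Muc2* (2.77). Of Paneth genes 4 of 11 rose (5 rose adjusted over the list alone, adjusted p = 0.461 with an estimated correlation) against Lgr5-high, such as the protease *Mmp7* (2.22), and against Lgr5-low 1 of 11 rose (2 rose adjusted over the list alone, adjusted p = 0.689 with an estimated correlation). The first day 6 library stood apart, and defensin and lysozyme genes made up 45.8% of its summed FPKM, against 26.9% in the second. Whether the enterocyte, enteroendocrine, goblet and Paneth lists moved with that library was not tested. Against Lgr5-low, among enterocyte genes 0 of 16 passed (0 adjusted over the list alone, median -0.10, adjusted p = 0.939 by camera). Among fatty acid oxidation genes 4 of 11 fell (7 fell adjusted over the list alone, adjusted p = 0.352 with an estimated correlation), and against Lgr5-high 1 of 11 rose, 4 fell and 6 did not pass (2 rose and 4 fell adjusted over the list alone, adjusted p = 0.561 by camera). The falls against Lgr5-low included the dehydrogenase *Acadm* (-1.20). The detoxifying enzymes *Ugt2a3* (-3.28), *Maob* (-3.17), *Rdh7* (-3.27) and *Ugt1a9* (-5.37) fell, the last sharing exons with its family and so uncertain, as did the arginase *Arg2* (-3.15). *Edn2* (-3.65 and -3.80) and *Hsd17b13* (-2.60 and -3.15) fell and *Cbr3* (5.37 and 5.29) rose against both gates. By limma 2828 genes passed against Lgr5-high (1298 higher, 1530 lower), and 1479 against Lgr5-low (802 higher, 677 lower). The balance depended on the scaling: 45.9% were higher against Lgr5-high, 56.1% with median-of-ratios scaling, 28.6% with equal FPKM sums and 56.8% without the 2 libraries that stood apart. Against Lgr5-low it was 54.2%, 38.5% with equal sums and 64% without these libraries. Against both gates 1111 genes passed in 1 direction (630 higher, 481 lower), uncorrected for the shared day 6 libraries. These counts fell without each library in turn, but 1 library in a group is too few to judge lists such as cell cycle genes.

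In organoids the question was what differed in culture with the *Mettl3* deletion after treatment for 2 days. WT organoids received ethanol and knockout organoids 4-OHT, so the drug and the deletion are not separable in this comparison. All tested interferon response genes and most goblet and enteroendocrine markers were higher, and most enterocyte genes were lower. *Isg15* rose by 5.16 ± 0.21, at 95.3 ± 29.9 against 1.62 ± 0.117 FPKM (SD, n = 2; limma adjusted p = 1.51e-04). *Clca1*, a goblet cell secreted protein, rose by 3.10 ± 0.09, at 83.9 ± 7.06 against 8.89 ± 0.652 FPKM (adjusted p = 3.42e-05). *Olfm4* changed by -1.19 ± 0.13, at 222 ± 6.72 against 507 ± 57.5 FPKM (adjusted p = 0.00139), and *Lgr5* by -0.63 ± 0.08, at 9.39 ± 0.225 against 15.1 ± 0.790 FPKM (adjusted p = 0.00214). Each called gene named here had both knockout libraries on one side of both WT libraries. In the interferon response list 18 of 18 rose (18 rose adjusted over the list alone, adjusted p = 0.504 with an estimated correlation). Higher members were the transcription factor *Irf7* (2.85) and *Ifit1* (3.31), *Ifit3* (3.53) and *Oasl2* (3.16). Outside the list rose *Ifit1bl1* (4.08), *Ifi27l2a* (3.72) and *Slfn2* (3.39). Among goblet genes 7 of 8 rose (7 rose adjusted over the list alone, adjusted p = 0.504 with an estimated correlation). The rises included *Zg16* (2.60) and *Fcgbp* (1.20). Among enteroendocrine genes 9 of 13 rose (10 rose adjusted over the list alone, adjusted p = 0.491 with an estimated correlation). Among the risers were the hormones *Cck* (1.52) and *Gcg* (1.41). Of Paneth genes 4 of 11 rose (5 rose adjusted over the list alone, adjusted p = 0.544 with an estimated correlation). Those that rose included *Mmp7* (1.36) and *Ang4* (1.25). Of fetal-like genes and YAP targets 6 of 9 rose (6 rose adjusted over the list alone, adjusted p = 0.491 with an estimated correlation). Higher members were *Anxa1* (2.15), *S100a6* (2.04) and *Areg* (1.66). In the immediate early list 12 of 17 rose (13 rose adjusted over the list alone, adjusted p = 0.504 with an estimated correlation). The rises included *Junb* (0.81) and the heat shock genes *Hspa1a* (1.44) and *Hspa1b* (1.34), which are near-identical copies.

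The falls in knockout organoids held enterocyte genes such as *Rbp2*. For enterocyte genes 9 of 15 fell (10 fell adjusted over the list alone, adjusted p = 0.544 with an estimated correlation). The falls included the protease *Mep1a* (-1.39) and *Rbp2* (-1.33). Among fatty acid oxidation genes 5 of 10 fell (7 fell adjusted over the list alone, adjusted p = 0.544 with an estimated correlation). Among cholesterol synthesis genes 8 of 14 fell (8 fell and 1 rose adjusted over the list alone, adjusted p = 0.544 with an estimated correlation). The falls included the synthases *Lss* (-0.71) and *Fdps* (-0.54). The largest falls held the glucuronosyltransferases *Ugt1a9* (-4.91), *Ugt1a5* (-4.79) and *Ugt2b5* (-2.42), the first pair sharing exons and so uncertain. They also held the cytochromes *Cyp3a25* (-2.26) and *Cyp2b10* (-2.24), the digestive protease *Ctrb1* (-3.50) and the protease inhibitor *Spink1* (-2.12). Of the stem cell markers 2 of 23 rose, 7 fell and 14 did not pass (3 rose and 8 fell adjusted over the list alone, adjusted p = 0.590 with an estimated correlation). Of cell cycle genes 2 of 29 rose, 8 fell and 19 did not pass (2 rose and 9 fell adjusted over the list alone, adjusted p = 0.590 with an estimated correlation). Among p53 targets 2 of 17 rose, 5 fell and 10 did not pass (4 rose and 6 fell adjusted over the list alone, adjusted p = 0.590 by camera), with *Gdf15* higher (0.58) and *Zmat3* lower (-0.59). In the m6A machinery 5 of 17 rose, 1 fell and 11 did not pass (5 rose and 1 fell adjusted over the list alone, adjusted p = 0.769 by camera), with the readers *Ythdf2* (0.79) and *Ythdf1* (0.61) and the writer subunit *Rbm15* (0.91) higher. Of the 4 factors used later, *Purb*, a single-strand nucleic acid binding protein, changed by -0.60 (adjusted p = 0.0109) and *Klf9* by 0.40 (adjusted p = 0.00667). The others, *Ascl2* (0.09, adjusted p = 0.403) and *Fosb* (-0.06, adjusted p = 0.839) did not pass. Nor did *Mki67* (0.10, adjusted p = 0.665), *Myc* (0.31, adjusted p = 0.124) and *Cdkn1a* (-0.13, adjusted p = 0.433). By limma 3570 of 12657 genes passed, 2109 higher and 1461 lower, 394 of them by at least 2-fold. The count fell without each library in turn, with 1 library left in a group. The higher genes were 59.1% of the calls, and 41% after scaling to equal FPKM sums. The 10 genes with most signal took 16.1% and 15.7% of the summed FPKM in knockout and 16.2% and 15.9% with AKF, against 12.3% and 11.7% in WT and 12.2% and 13.1% with AKFP. The top gene was the short RNA *Gm23935* in knockout and AKF libraries and *mt-Co1* in the others. Whether library preparation differed along these lines was not tested.

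Whether tissue and organoids changed alike was compared across genes tested in both, with no library in common. For the Lgr5-high gate at day 4 the changes had Pearson r = 0.427 across genes (jackknife SE 0.075, 0.353 to 0.45 with 1 library left out), and for Lgr5-low r = 0.471 (SE 0.089, 0.396 to 0.48). Of the genes called in both Lgr5-high cells and organoids, 57 were higher in both (14.3 for independent calls), among them *Isg15*, 23 lower in both (4.2), 2 higher in tissue and lower in organoids (10) and 4 the other way (6). Of the 18 interferon genes 7 rose in Lgr5-high cells, 4 in Lgr5-low and 18 in organoids. Of the immediate early genes 5 fell in Lgr5-high cells and 12 rose in organoids.

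The AKF organoids address whether *Ascl2*, *Klf9* and *Fosb* together change the knockout. Only *Ascl2* of the 3 rose (chromosome 7, 142966829 to 142969264), by 1.56 ± 0.07, at 37.7 ± 1.28 against 12.2 ± 0.255 FPKM (SD, n = 2; limma adjusted p = 0.00199), in both AKF libraries. *Klf9*, a Krüppel-like transcription factor, stood at 10.9 ± 0.332 against 7.85 ± 0.0828 FPKM (0.43, adjusted p = 0.201) and *Fosb* at 26.2 ± 0.648 against 31.8 ± 9.03 FPKM (-0.24, adjusted p = 1.0), neither past the test. *R3hdml* rose by 1.19 ± 0.07 (adjusted p = 0.00257). *Tmed2*, a cargo receptor of the early secretory pathway, rose by 0.72 ± 0.07 (adjusted p = 0.0237), each in both libraries. *Kctd12*, an auxiliary subunit of GABA receptors, read 3.0 and 2.64 FPKM in knockout and was listed at 0 in both AKF libraries (adjusted p = 0.00199), as it was in both WT libraries. The other calls, the predicted gene *Gm47299* (5.30 and 7.72 FPKM against 0.115 and 0.105) and the small nucleolar RNA *Snord16a* (4.29 and 5.38 against 0.016 and 0.016), lie outside the naming rule and were chosen after their values were seen. Of the interferon genes 0 of 18 passed (0 adjusted over the list alone, median -0.02, adjusted p = 0.929 by camera), with *Isg15* at -0.13 (adjusted p = 1.0). *Olfm4* (0.23) and *Lgr5* (0.18) did not pass (adjusted p = 1.0 for both). Of the stem cell markers 1 of 23 rose (3 rose and 1 fell adjusted over the list alone, adjusted p = 0.601 with an estimated correlation), the member being *Ascl2*. Of the 4 factors 1 of 4 rose (2 rose adjusted over the list alone, adjusted p = 0.299 with an estimated correlation). By limma 6 of 12657 genes passed, 5 higher and 1 lower, with 582 at an unadjusted p under 0.05.

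The AKFP organoids add *Purb* to the same factors. They also differ in sex, and so in donor, from knockout organoids, so no change below can be ascribed to the factors alone. *Klf9* rose by 2.11 ± 0.07, at 37.2 ± 1.71 against 7.85 ± 0.0828 FPKM (SD, n = 2; limma adjusted p = 2.15e-05), and *Ascl2* by 0.61 ± 0.07, at 19.1 ± 0.108 against 12.2 ± 0.255 FPKM (adjusted p = 0.00299). *Fosb* was lower, at -1.42 ± 0.18 and 11.1 ± 1.85 against 31.8 ± 9.03 FPKM (adjusted p = 0.00384). *Purb* itself did not pass, at 0.19 and 18.0 ± 2.14 against 15.7 ± 1.97 FPKM (adjusted p = 0.257). *Olfm4* rose by 1.19 ± 0.13 to the level of WT organoids, at 507 ± 3.57 against 222 ± 6.72 FPKM (adjusted p = 0.00202). *Isg15* changed by -3.17 ± 0.21, at 9.42 ± 0.273 against 95.3 ± 29.9 FPKM (adjusted p = 3.83e-04). Each called gene named here had both AKFP libraries on one side of both knockout libraries. In the interferon response list 15 of 18 fell (17 fell adjusted over the list alone, adjusted p = 0.591 with an estimated correlation). The falls included *Oas1a* (-2.42) and *Irf7* (-2.39), and *Ifi27l2a* fell too (-4.27). Among immediate early genes 15 of 17 fell (16 fell adjusted over the list alone, adjusted p = 0.591 with an estimated correlation). The falls included *Junb* (-1.01) and *Atf3* (-0.92). Of cell cycle genes 16 of 29 rose (19 rose adjusted over the list alone, adjusted p = 0.591 with an estimated correlation). Among the risers were the ribonucleotide reductase subunit *Rrm2* (0.48) and the cyclin *Ccna2* (0.45). *Mki67* stood at 0.37 (adjusted p = 0.110). Of the stem cell markers 9 of 23 rose, 3 fell and 11 did not pass (13 rose and 4 fell adjusted over the list alone, adjusted p = 0.591 with an estimated correlation), with *Igfbp4* lower (-1.87) and *Lgr5* not past the test (0.25, adjusted p = 0.0522). Of Paneth genes 7 of 11 rose (7 rose adjusted over the list alone, adjusted p = 0.591 with an estimated correlation). Those that rose included the phospholipase *Pla2g2a* (5.43) and the defensins *Defa21* (2.32), *Defa22* (2.45) and, outside the list, *Defa32* (3.33), whose close copies make them uncertain. Of enteroendocrine genes 2 of 13 rose, 10 fell and 1 did not pass (2 rose and 10 fell adjusted over the list alone, adjusted p = 0.591 with an estimated correlation), with *Sct* (-1.46) and *Tac1* (-1.11) lower and *Nts* (2.65) higher. Among enterocyte genes 5 of 15 fell (7 fell adjusted over the list alone, adjusted p = 0.591 with an estimated correlation). The falls included *Fabp1* (-1.58) and *Anpep* (-1.26).

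Sex-linked genes also separated the AKFP organoids. *Xist*, the RNA that coats the inactive X chromosome, read 47.5 and 33.3 FPKM in the AKFP libraries and at most 0.02 in the other organoid libraries, a rise over knockout of 5.33 ± 0.16 (limma adjusted p = 1.72e-05, both libraries). The Y-linked genes *Eif2s3y* and *Ddx3y* were listed at 0 in both AKFP libraries and had means of 13.2 ± 0.369 and 6.68 ± 0.0507 FPKM (SD, n = 2) in knockout. Other large changes were the bile acid carrier *Fabp6* (4.10), the EGF family ligand *Ereg* (2.28) and the kinase *Ak4* (2.40) on the higher side. On the lower side were the neuritin *Nrn1* (-3.33), the fetal albumin-like *Afp* (-3.07) and *Exosc6* (-5.46), a single-exon exosome gene with uncertain values. By limma 3337 of 12657 genes passed, 1666 higher and 1671 lower, 413 of them by at least 2-fold. The count was 920 and 1541 without the first and second knockout library and 1589 and 950 without the first and second AKFP library. The higher genes were 49.9% of the calls, 69.3% after scaling to equal FPKM sums and 41.3% with median-of-ratios scaling.

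How far organoids with the factors lay back toward WT was measured over the 3570 genes called in knockout against WT organoids. The AKFP organoids differ in sex from the others, as *Xist* shows, so their values below cannot be ascribed to the factors alone. With AKFP, 832 of them (23.3%) were called in the opposite direction, *Isg15* and *Olfm4* among them, and 471 (13.2%) in the same direction. Of the 3570, 2367 (66.3%) were still called against WT in the knockout's direction, such as *Isg15*, *Lgr5* and *Purb*. Of the 9087 genes not called in the knockout, 2034 (22.4%) were called as well. With AKF, 3 (0.1%) were opposite and 3043 (85.2%) still called. The slope of the later change on the knockout change, corrected for the shared knockout libraries, was -0.185 for AKFP (jackknife SE 0.042, -0.217 to -0.166 with 1 library left out) and 0.019 for AKF (SE 0.064, -0.033 to 0.058). Across genes, which are not independent replicates, the covariance of the paired changes was -0.1168 for AKFP and -0.0106 for AKF, against -0.0204 for simulated unchanged groups, a difference of -0.0964 and 0.0098. The 2 knockout libraries could not be split further, and the counts of opposite calls are not corrected for sharing them.

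**Figure D2:**
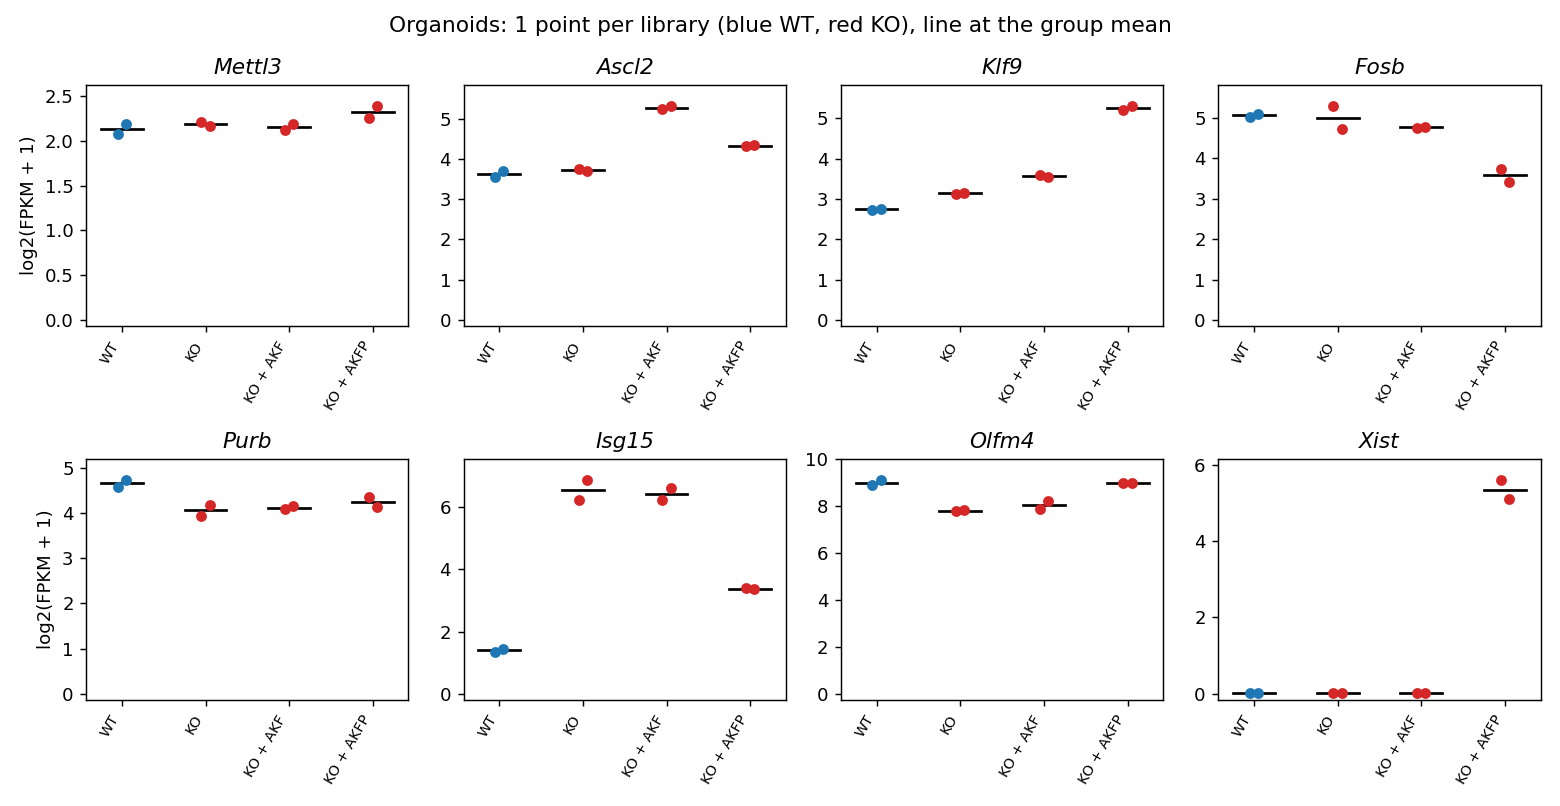
Each panel shows log2(FPKM + 1) of 1 gene in 4 organoid groups, 1 point per library (blue WT, red knockout) with a line at the group mean. *Ascl2* is highest with AKF, *Klf9* with AKFP, and *Purb* lies below WT in each knockout group. *Isg15* is lower with AKFP than in knockout but above WT, and *Xist* is seen with AKFP.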

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

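The tests of another mouse line or donor, of loss of the Y chromosome and of sequencing depth were chosen only after the results were seen. 2 genes stood out because their knockout change at day 4 differed between the gates in limma's test of that difference. *Hist2h2aa1* had a difference of -3.28 (adjusted p = 0.00519), with 9.67 and 7.84 FPKM in WT Lgr5-high and a listed 0 in both WT Lgr5-low libraries and in all day 4 knockout libraries. *Gm27640* had a difference of -3.87 (adjusted p = 0.00534), with 12.9 and 19.3 FPKM in WT Lgr5-high, 0 and 0.148 in WT Lgr5-low and 0.141 and 0 in knockout Lgr5-high. Both values rest on libraries listed at or near 0, so they are fitted differences and not folds.

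Other named genes stood out because, within the gate given, both day 4 knockout libraries lay on one side of both WT libraries and both knockout organoid libraries on the other side of WT organoids, a difference that was not tested in any of these cases. In Lgr5-high cells *Cdkn1a* rose by 1.48 (limma adjusted p = 0.0497), and in organoids it stood at -0.13 (adjusted p = 0.433). *Klf9* stood at -1.52 in Lgr5-high (adjusted p = 0.149) and -0.23 in Lgr5-low (adjusted p = 0.902), and at 0.40 in organoids (adjusted p = 0.00667). The macrophage marker *Cd68* stood at -0.32 in Lgr5-high (adjusted p = 0.679) and -0.45 in Lgr5-low (adjusted p = 0.650), and at 1.16 in organoids (adjusted p = 0.00138). *Fdps*, of cholesterol synthesis, stood at 0.78 in Lgr5-high (adjusted p = 0.147) and -0.54 in organoids (adjusted p = 0.00272).

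AKFP organoids differed from knockout organoids in 3337 genes, where AKF organoids differed in 6. Loss of the Y chromosome in culture is excluded, because *Xist*, which male cells do not express, read at least 33.3 FPKM in both AKFP libraries. The AKFP organoids differ in sex, and so in donor, from knockout organoids. Their 4 Y-linked genes summed to 0 in both libraries, against a mean of 23.12 FPKM in knockout. How many of the 3337 calls this explains stays open, as the factors differ too. Genes switched fully on or off on the autosomes numbered 8 in AKFP against knockout, 7 in knockout against WT and 3 in AKF against knockout, so effects of another line and of the factors cannot be told apart from these counts. The effect of adding *Purb* stays open as well and was not separable, because its transcript level did not differ from knockout (0.19, limma adjusted p = 0.257) and the groups differ in sex. An added copy without the transcript parts counted would not add to these values, nor to those of *Fosb*, so they do not show whether the factor was expressed, which was not tested.

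The first libraries of knockout Lgr5-high at day 4 and of knockout at day 6 stood apart from their partners, with 1712 and 894 genes at least 2-fold apart against 238 to 500 in the other tissue groups. A larger share taken by defensin and lysozyme genes is excluded as the whole cause, since 89.8% and 96.2% of these genes stayed 2-fold apart without them. A lower depth is excluded as the shared cause. The ratio of first to second library was 1.5 at day 6, where the first library was the deeper. It was 0.91 for Lgr5-high at day 4, below the 1.41 to 1.62 of the other groups, so a small effect of depth on that library is not excluded. A transcript length bias is consistent with the values: after a length trend was taken out 40% and 49.2% stayed 2-fold apart, against 82.3% to 93.2% in the other groups. Whether the animals differed was not tested.

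Immediate early genes were lower in knockout tissue at day 4 and higher in knockout organoids, with list means of -1.11 in Lgr5-high, -0.96 in Lgr5-low and 0.53 in organoids. Scaling of FPKM between libraries is excluded as the cause, since at least 0.81 of each change was kept under 3 other scalings. These genes respond to cell dissociation, and variation in handling that is independent of the knockout could add to the change: the list mean differed by up to 0.28 between 2 WT libraries of a gate. Handling and knockout cannot be told apart here, because the labels do not say which libraries were dissociated together. A knockout effect that differs between tissue and culture stays open and was not tested.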

How the results depend on the processing

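Equal FPKM sums, the fit without the 2 tissue libraries that stood apart, the transcript length trend and the slope over all genes were chosen after seeing the data. Of 818 results for single genes and lists 0 reversed, a weak check as calls rarely reverse. Fewer were run with the stricter filter, with only the compared groups in the fit, with the length trend taken out (249 kept, 2 lost) and with libraries left out. Among all calls, 1 reversed with quantile normalization for AKF against WT and 1 for AKFP against WT. Of the 818, 675 kept their call or value, 71 lost the call and 72 moved in value with equal FPKM sums. These were 781, 10 and 27 with median-of-ratios scaling, 798, 13 and 7 with a pseudocount of 0.1 and 795, 11 and 12 with 5. They were 718, 4 and 45 with a filter at 5 FPKM and 613, 113 and 92 with none, where more genes are tested. Leaving out 1 library weighed more in many cases: 54 kept and 70 lost the call without the second WT Lgr5-high library, 64 and 65 without the first, 40 and 67 without the second WT Lgr5-low library and 50 and 59 without the first. Without the first and second knockout library these were 15 and 19 and 36 and 2 in Lgr5-high at day 4, 6 and 19 and 4 and 20 in Lgr5-low, and 106 and 40 and 149 and 11 at day 6. In organoids the losses ran from 5 without the second AKF library (201 kept) to 41 without the second AKFP library (204 kept). The correlation across genes of the gate differences stayed between 0.506 and 0.702 with 1 library left out, that of tissue and organoid changes between 0.353 and 0.45 for Lgr5-high and 0.396 and 0.48 for Lgr5-low, and the slope for AKFP between -0.217 and -0.166. The slope for AKF, 0.019, turned to -0.004 without the first knockout organoid library and to -0.033 without the second AKF library, with a highest value of 0.058. Counts below are genes past limma's threshold, and the cause of each shift was not tested unless fewer libraries or more tested genes are named.

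Against 155 genes between the WT gates, no filter gave 32, quantile normalization 329, equal FPKM sums 57, the length trend 398, leaving out the 2 libraries that stood apart 412 and only the compared groups in the fit 1432. Against 136 for knockout in Lgr5-high at day 4 these settings gave 29, 287, 34, 333, 68 and 0, with 2182 genes at an unadjusted p under 0.05 in limma's fit of all groups. Against 61 in Lgr5-low they gave 21, 143, 6, 235, 253 and 1, and a pseudocount of 0.1 gave 38. Against 0 between the knockout gates, a pseudocount of 5 gave 1, no filter 5, the filter at 5 FPKM 1, median-of-ratios scaling 3, quantile normalization 1, the length trend 125 and leaving out the 2 libraries 1. Against 2 for the difference between the gates, a pseudocount of 0.1 gave 0, no filter 7, the filter at 5 FPKM 0 and leaving out the 2 libraries 0. At day 6 equal FPKM sums gave 1809 against 2828 (Lgr5-high), and 628 against 1479 (Lgr5-low). For KO 6 d against both WT gates they gave 478 against 1111. The length trend gave 2436 against Lgr5-low and 1847 against both. In organoids no filter gave 13 against 6 for AKF, and only the compared groups in the fit gave 1800 against 3239 for AKFP against AKF. At day 3 the counts (KO 3 d vs WT, Lgr5-high, genes at least 2-fold apart) were 196, 549 with a pseudocount of 0.1, 72 with 5 and, against the first and second WT library alone, 325 and 245, where these WT libraries were apart in 238. In the other gate (KO 3 d vs WT, Lgr5-low, genes at least 2-fold apart) they were 199, 596, 75, 331 and 272, and the WT libraries were apart in 290.

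Leaving out 1 library in turn, a lone library being assumed to vary like the other groups, gave 0 to 7 genes between the WT gates, 1 to 699 for knockout at day 4 in Lgr5-high, and 3 to 6 in Lgr5-low. It gave 0 to 1736 between the knockout gates and 0 to 3 for the difference between gates. It gave 588 to 2327 at day 6 against Lgr5-high, 254 to 1130 against Lgr5-low, and 235 to 905 against both. In organoids it gave 1732 to 1933 for knockout organoids, 7 to 9 for AKF against knockout, 920 to 1589 for AKFP against knockout. It gave 973 to 2880 for AKFP against AKF, 2138 to 2929 for AKF against WT and 3400 to 4104 for AKFP against WT.

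Scaling also moved the share of higher calls, given beside each count. The median change of all genes went from -0.162 at day 6 against Lgr5-high to -0.021 with median-of-ratios scaling and -0.46 with equal sums. With equal sums it went from -0.079 to -0.291 against Lgr5-low, from -0.02 to -0.131 in Lgr5-high at day 4, from 0.042 to 0.15 for AKFP against knockout and from 0.044 to 0.147 for AKFP against AKF.

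The replicate numbers were not taken to pair the libraries, because not every pair of groups had a correlation over 0.1. Deviations of same-numbered libraries correlated at 0.02 to 0.52 over 10 pairs of tissue groups (7 over 0.1), with 0.44 for the WT gates, 0.34 for the knockout gates at day 4 and 0.52 for knockout Lgr5-high at day 4 with day 6. A shared effect of the number in tissue is thus not excluded. They correlated at -0.04 to 0.09 over 6 pairs of organoid groups (0 over 0.1). With the number as a replicate block, counts were 432 between the WT gates, 283 and 109 for knockout at day 4 in Lgr5-high and Lgr5-low, 276 between the knockout gates and 2 for the difference. They were 3561, 1914 and 1451 at day 6 (against Lgr5-high, Lgr5-low and both), and 3634, 5, 3630, 3504, 3951 and 5645 for the organoid comparisons in the order above. FPKM carry no counts, so counting error at low values was not modelled. In simulated data changes of 1.5-fold were called in 2% of cases in Lgr5-high cells at day 4 and in 62% in organoids.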

Other observations

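The genes given as examples at day 3 and in the lists below were chosen after their values were seen. At day 3, with 1 knockout library per gate and no test, some genes that passed at later days lay on the same side of WT. *Phlda3* read 10.6 FPKM in Lgr5-high and 7.345 in Lgr5-low, against 1.305 and 1.62 and 0.685 and 0.447 in the WT libraries of these gates. *Isg15* read 6.19 and 8.41 against 1.22, 1.25, 1.94 and 7.02. *Lgr5* stood at 9.18 in Lgr5-high against 10.1 and 10.4. The median log2 differences in Lgr5-high and Lgr5-low were 0.65 and 0.61 for p53 targets, 0.56 and 0.70 for goblet genes, 0.61 and 0.69 for enteroendocrine genes and 0.56 and 0.38 for cholesterol synthesis (percentile 100 of 10000 matched random lists for each). Ribosome biogenesis genes stood at 0.33 and 0.41 (percentile 100 for both) and cell cycle genes at 0.33 and 0.19 (100 and 99.4). Fetal-like genes and YAP targets stood at 0.34 and 0.39 (99.7 and 99.8). Interferon response genes stood at 0.25 and 0.23 (percentiles 99.8 and 99) and fatty acid oxidation at -0.35 and -0.43 (percentile 0). Random lists were drawn gene by gene, so lists whose genes vary together can reach the ends without a knockout effect. The percentiles are thus descriptive. Other cell type lists lay lower: Paneth genes at -0.41 and 0.18 (percentiles 0 and 97.2), tuft genes at 0.10 and -0.34 (72.7 and 0.1) and enterocyte genes at -0.02 and -0.28 (17.4 and 0.1). The medians depended on the pseudocount and on the WT library. With pseudocounts of 0.1 and 5, those of interferon response genes were 0.53 and 0.08 in Lgr5-high and 0.47 and 0.10 in Lgr5-low. Those of p53 targets were 0.67 and 0.31 and 0.71 and 0.30, and of enteroendocrine genes 0.77 and 0.43 and 0.72 and 0.57. Against the first and second WT library alone, goblet genes stood at 0.28 and 0.84 in Lgr5-high and 0.73 and 0.84 in Lgr5-low, and enteroendocrine genes at 0.16 and 1.02 and at 0.37 and 0.94. Those of p53 targets were 0.59 and 0.44 and 0.64 and 0.58 and of interferon response genes 0.24 and 0.26 and 0.31 and 0.12. Immediate early genes stood at -0.15 and -0.17 (percentiles 0.4 and 1.9), and stem cell markers at -0.09 and 0.28 (percentiles 0.6 and 100), the gates lying on opposite sides of 0. Against single WT libraries the former were -0.23 and -0.16 and -0.34 and -0.06, and the latter -0.04 and -0.16 and 0.2 and 0.27. In Lgr5-high 110 genes were at least 2-fold higher and 86 lower, and in Lgr5-low 110 and 89, each from the mean of 2 WT libraries. A single library has no spread of its own against which to judge a gene.

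At day 6, among genes of the integrated stress and unfolded protein response 5 of 12 rose (5 rose adjusted over the list alone, adjusted p = 0.223 with an estimated correlation) against WT Lgr5-high by limma. Against Lgr5-low 6 of 12 rose (6 rose adjusted over the list alone, adjusted p = 0.307 with an estimated correlation). A member that rose against both gates was the serine synthesis enzyme *Psat1* (1.5 and 1.99). Among cell death genes 3 of 10 rose (3 rose adjusted over the list alone, adjusted p = 0.381 with an estimated correlation) against Lgr5-high, and against Lgr5-low 1 of 10 rose (2 rose and 1 fell adjusted over the list alone, adjusted p = 0.689 by camera). The rises over Lgr5-high included the necroptosis genes *Mlkl* (1.78) and *Ripk3* (0.92) and the pore former *Gsdmd* (1.99). Among reserve stem cell markers 3 of 5 fell (3 fell adjusted over the list alone, adjusted p = 0.462 with an estimated correlation) against Lgr5-high, and against Lgr5-low 0 of 5 passed (0 adjusted over the list alone, median -0.16, adjusted p = 0.910 by camera). The falls against Lgr5-high included *Hopx* (-1.04) and *Lrig1* (-1.26). Of the Notch and secretory choice genes 1 of 10 rose, 3 fell and 6 did not pass (1 rose and 3 fell adjusted over the list alone, adjusted p = 0.638 by camera) against Lgr5-high, with *Atoh1*, the factor of the secretory lineage, higher (2.0) and the Notch target *Nrarp* lower (-1.87). Against Lgr5-low 1 of 10 rose, 1 fell and 8 did not pass (2 rose and 2 fell adjusted over the list alone, adjusted p = 0.910 by camera). In cholesterol synthesis 4 of 14 rose (6 rose adjusted over the list alone, adjusted p = 0.427 with an estimated correlation) against Lgr5-high, and 1 of 14 rose (1 rose adjusted over the list alone, adjusted p = 0.771 by camera) against Lgr5-low. In ribosome biogenesis 4 of 16 rose (4 rose adjusted over the list alone, adjusted p = 0.771 with an estimated correlation) against Lgr5-low, with *Rrs1* (1.35), and against Lgr5-high 0 of 16 passed (0 adjusted over the list alone, median -0.27, adjusted p = 0.946 by camera). Of the MHC class II genes 1 of 7 fell (1 fell adjusted over the list alone, adjusted p = 0.561 by camera) against Lgr5-high, the fall being *H2-DMa* (-2.23), and against Lgr5-low 1 of 7 fell (1 fell adjusted over the list alone, adjusted p = 0.771 by camera). For tuft genes 0 of 8 passed (0 adjusted over the list alone, median 0.68, adjusted p = 0.638 by camera) against Lgr5-high, and 0 of 8 passed (0 adjusted over the list alone, median -0.06, adjusted p = 0.956 by camera) against Lgr5-low. Of Wnt targets 1 of 17 rose, 7 fell and 9 did not pass (1 rose and 8 fell adjusted over the list alone, adjusted p = 0.441 with an estimated correlation) against Lgr5-high, and 3 of 17 rose, 1 fell and 13 did not pass (3 rose and 1 fell adjusted over the list alone, adjusted p = 0.689 with an estimated correlation) against Lgr5-low. Their medians, -0.51 and 0.32, lay on opposite sides of 0. In the intestinal region list 2 of 5 rose, 1 fell and 2 did not pass (2 rose and 2 fell adjusted over the list alone, adjusted p = 0.638 by camera) against Lgr5-high, with the ileal bile acid transporter *Slc10a2* (3.02) and *Fabp6* (2.85) higher and *Gata4*, a factor of the proximal intestine, lower (-0.82). The median of that list was -0.03 and its mean 0.78, on opposite sides of 0. Against Lgr5-low 1 of 5 rose, 1 fell and 3 did not pass (1 rose and 2 fell adjusted over the list alone, adjusted p = 0.910 by camera). In the m6A machinery 1 of 16 rose, 1 fell and 14 did not pass (1 rose and 0 fell adjusted over the list alone, adjusted p = 0.983 by camera) against Lgr5-high, with the reader *Ythdf2* higher (1.02) and *Rbm15b* lower (-1.04). Against Lgr5-low 1 of 16 rose (1 rose adjusted over the list alone, adjusted p = 0.910 by camera), the rise being *Ythdf2* (1.41). Of the 5 immune cell genes tested in tissue 0 passed against Lgr5-high, and against Lgr5-low 1 fell, *Itgam* (-1.09, adjusted p = 0.0440). The stromal gene tested, *Vim* (2.30, adjusted p = 0.0959), did not pass at day 4 in Lgr5-high and rose in knockout organoids (0.77, adjusted p = 0.00197).

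The organoids with factors were also set against WT organoids by limma. With AKF, 3839 genes passed (2228 higher, 1611 lower, a share of 58% higher that was 40.8% with equal FPKM sums), with *Isg15* at 5.03 ± 0.21 (adjusted p = 9.95e-05), *Clca1* at 3.44, *Ly6a* at 3.33 and the monoamine oxidase *Maob* at -2.29. Of the interferon response genes 18 of 18 rose (18 rose adjusted over the list alone, adjusted p = 0.464 with an estimated correlation). With AKFP, 5491 genes passed (3114 higher, 2377 lower, a share of 56.7% higher that was 48.6% with median-of-ratios scaling). Of the interferon response genes 10 of 18 rose (12 rose adjusted over the list alone, adjusted p = 0.709 with an estimated correlation), *Isg15* standing at 1.99. Among enterocyte genes 13 of 15 fell (14 fell adjusted over the list alone, adjusted p = 0.696 with an estimated correlation) with AKFP. Among Paneth genes 8 of 11 rose (8 rose adjusted over the list alone, adjusted p = 0.696 with an estimated correlation). With AKFP *Olfm4* (0.00, adjusted p = 0.990) did not pass. *Lgr5* (-0.38, adjusted p = 0.00847) and *Purb* (-0.41, adjusted p = 0.0270) stayed below WT in both libraries. AKFP and AKF organoids differed in 3239 genes (1626 higher, 1613 lower with AKFP, a share of 50.2% higher that was 68.6% with equal FPKM sums and 39.4% with median-of-ratios scaling). *Ascl2* was lower with AKFP than with AKF (-0.94 ± 0.07, adjusted p = 6.43e-04) and *Klf9* higher (1.68 ± 0.07, adjusted p = 4.72e-05), while *Purb* (0.13, adjusted p = 0.433) did not pass. Cell cycle genes gave 19 rises of 29 with AKFP over AKF and 10 that did not pass (24 rose adjusted over the list alone, adjusted p = 0.702 with an estimated correlation). The counts against WT were 2230 and 2138 without the first and second WT library for AKF and 3400 without the first WT and 3493 without the second AKFP library for AKFP. Those of AKFP against AKF were 1313, 1562 and 973 without the first AKF, the first AKFP and the second AKFP library.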
